A study of Mus musculus with 2 samples.

How the data were processed

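ERRα ChIP-seq was carried out on C2C12 myotubes over-expressing PGC-1α, with 1 immunoprecipitated library and 1 input library; groups were taken from the sample titles. Per the submitters' processing notes, Bowtie 0.12.7 and the mm9 build were used; the last peak on chromosome 1 ends beyond the last gene of that chromosome on the later build GRCm38. The peak caller, its threshold and any read filter are not given in the sources used here. The deposited peak list has 3 columns, the chromosome, start and end of each window, and no score, fold enrichment, p-value, read count or gene name. Its values are positions, and all 3225 windows were 200 bp wide with starts at whole multiples of 25 bp. The source of the fixed width and step is not given in the sources used here; because they are the same for every window, the width does not tell peaks apart and distances are resolved to 25 bp. The list is the result of the comparison of the immunoprecipitate with input; read depth is unknown for both libraries, no replicate exists, and a peak absent from the list cannot be told from a peak missed at the depth used. The number of value columns belonging to other samples was 0.

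Positions are printed on mm9, counted from 1. The gene table at hand was the RefSeq annotation of GRCm38.p6, another build, and it was used for the number of protein-coding genes per chromosome, 21887 on the 21 chromosomes, and for no position. Neither the sequence nor an annotation of mm9 was used here. Peaks were therefore not assigned to genes, and the distance to transcription start sites, exon and intron shares, the 24 gene lists (500 entries, mitochondrial, muscle and other cell type genes) and the 15 motifs (ERR response element, SP1 and others) that had been fixed before the data were examined were not analysed here. Comparisons by score could not be made either, because the list gives none.

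Peaks per chromosome were compared with the share of protein-coding genes by a chi-square statistic against 100000 multinomial draws and, per chromosome, by a two-sided exact binomial test with Benjamini-Hochberg adjustment over chromosomes. Ratios carry exact (Clopper-Pearson) 95% intervals. Clustering was measured as the share of peaks with another window start within 10 kb, against 10000 placements in which each peak was moved at random between the first and last peak of its chromosome in steps of 25 bp; overlaps were allowed. Runs join windows separated by at most 10 kb, and long runs are those longer than any run in the placements (more than 5 peaks). For each long run, the share of peaks with another peak at a fixed distance (500 to 5000 bp in steps of 25 bp, within 25 bp) was maximised over distances and compared with 10000 random arrangements of as many windows over the same length, at least 250 bp apart. This test was one-sided, and its p-values were adjusted over the 8 long runs. Correlations were tested with 100000 permutations, two-sided. P-values here compare the list with random lists and say nothing of what a repeat of the experiment would give.

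The rule for named items, fixed before the data were examined, took the 10 highest-scoring peaks or, without scores and with equal widths, those in the densest 100 kb, the chromosomes with the highest and lowest ratio, the densest cluster, and genes of the lists and of the ERR network. The gene parts had no assignment to work on. The clustering windows, autosomes alone, merging of overlapping rows and placement near peaks were alternatives fixed before the data were examined. The test of runs, the empty bins, the correlations, and the alternatives that count runs once, leave out long runs, use the span or leave out receptor genes were added afterwards.

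Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The steps were tested on simulated data: with a doubled weight (factor 2) on chromosome 15, the chromosome was called higher in 100 of 100 lists of 3225 peaks, while 6 of 100 unchanged lists had any chromosome called. Peaks of these lists were drawn independently, with the span as the weight of each chromosome in place of its gene share. The rate of false calls for clustered peaks was not tested. Evenly spaced runs of 12 peaks were called in 100 of 100 simulations and random runs in 2 of 100. These simulations used a nearly exact spacing, fewer random arrangements than the test of the list, and no adjustment over runs. How often shorter or less even runs would be called was not tested. Of 20 random placements, 0 were called clustered, and all 20 were called after some of their peaks were moved beside others.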

Results

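Binding of ERRα was mapped in C2C12 myotubes that over-expressed PGC-1α. C2C12 is a mouse myoblast line that fuses into multinucleated myotubes when serum is lowered. ERRα (gene Esrra) is an orphan nuclear receptor that regulates genes of mitochondrial energy metabolism, and PGC-1α (gene Ppargc1a) is a transcriptional coactivator that partners with it. The cells were differentiated for 72 h in medium with 2% horse serum and then infected for 48 h with an adenovirus carrying tagged PGC-1α. Chromatin immunoprecipitation with a monoclonal ERRα antibody was followed by sequencing (ChIP-seq), and whole-cell extract DNA from the same kind of culture served as the input background. There was 1 immunoprecipitated library and 1 input library. The comparison therefore has no replicate check, and the values that follow describe this peak list, in which peaks are not replicates of an experiment.

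The immunoprecipitate against input gave 3225 ERRα peak windows, which together covered 645 kb of the mm9 genome. Each window was 200 bp wide, no 2 windows overlapped, and the closest pair of window starts on a chromosome lay 250 bp apart. The median distance between neighbouring window starts was 264 kb, with quartiles of 44.5 kb and 868 kb. Peaks lay on all 19 autosomes, where 3183 were found, and on the sex chromosomes, with 40 on X and 2 on Y. The list carried no height, enrichment or read count per peak and the depth of both libraries is unknown, so peaks could not be ranked by strength.

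**Figure D1:**
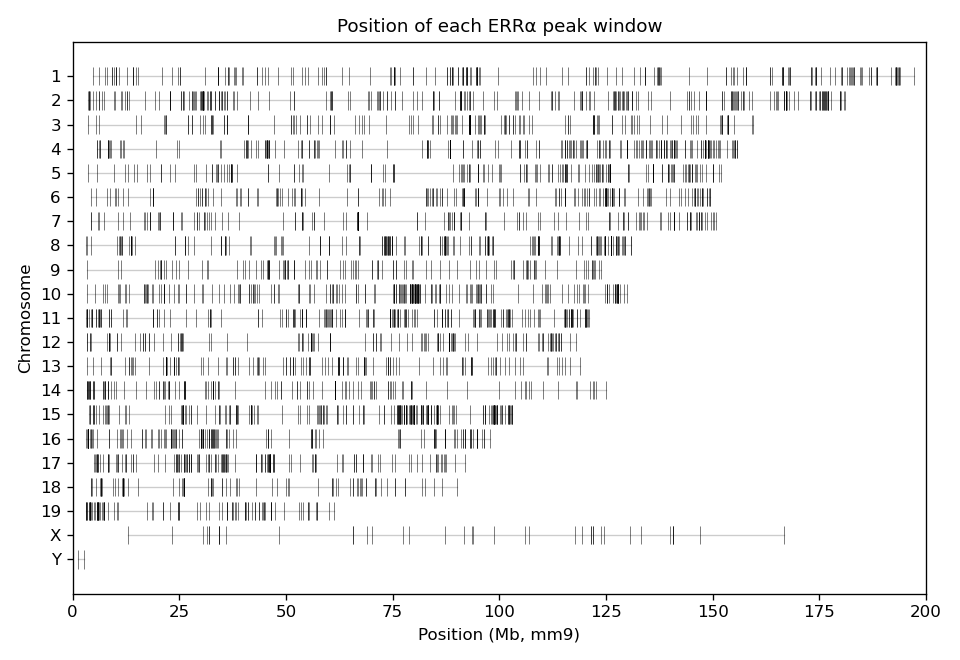
Position of each of the 3225 ERRα peak windows (vertical ticks, position in Mb on mm9) on each chromosome (rows); the grey line runs from the first to the last peak of the chromosome. Ticks crowd together in parts of the autosomes and leave other parts empty, and X carries 40 widely spaced peaks; at this scale a run of peaks within 100 kb merges into a single tick.

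The series asks which sites of the genome recruit ERRα, so the spread of peaks over chromosomes was compared with the spread of protein-coding genes. Chromosome 15 was the richest in peaks for its gene content, with 214 peaks where 114 were expected from its share of genes, a ratio of 1.87 (95% interval 1.64 to 2.13). Chromosome 8 followed with 250 peaks and a ratio of 1.63 (1.44 to 1.83), of which 74 peaks lay in a single block of 85.0 kb. Peaks were scarce on chromosome X, with 40 observed against 142 expected and a ratio of 0.28 (0.20 to 0.38), and on chromosome 7, with 162 against 299 and a ratio of 0.54 (0.46 to 0.63). With the span from the first to the last peak as the expected share, chromosome 7 had a ratio of 0.87 and was not called. Chromosome Y had the lowest ratio by genes, 0.053 (0.0064 to 0.19), but this rests on 2 peaks that lie within 1.37 Mb, against 256 genes of the other build. Whether mm9 holds those genes was not checked, so the low ratio does not show scarcity on Y. By the span between the 2 peaks the ratio was 1.15 and was not called.

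In all, 11 of the 21 chromosomes departed from their gene share in an exact binomial test after Benjamini-Hochberg adjustment over chromosomes. The 6 with more peaks than expected were chromosomes 4, 8, 10, 12, 15 and 16, and the 5 with fewer were 7, 9, 11, X and Y. Chromosomes 10 and 16 stood at the same level, with ratios of 1.38 (1.20 to 1.57) and 1.38 (1.16 to 1.62). Chromosome 12 had a ratio of 1.30 (1.09 to 1.54) and chromosome 9 a ratio of 0.63 (0.52 to 0.76). The calls of chromosomes 4 and 11 were marginal, with ratios of 1.16 and 0.86 and an adjusted exact binomial p of 0.049 for each. Chromosome 7 carries 417 olfactory and vomeronasal receptor genes, and without receptor genes of those families in the expected share its ratio was 0.64 and stayed called, while chromosomes 12 and 4 fell to 1.21 and 1.11 and were no longer called.

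The departure over all chromosomes was larger than in any of 100000 multinomial draws from the gene shares (chi-square 404, permutation p = 1e-05, the smallest that the draws can give). With the span from the first to the last peak as the expected share, chromosome 11 changed direction and was called higher, at a ratio of 1.36. Chromosomes 12, 16 and 7 then had ratios of 0.89, 1.15 and 0.87, and none of these passed the test, nor did Y. The intervals and the binomial test cover counting error only and treat peaks as independent, which they are not, in dense blocks or elsewhere. Without the 8 long runs, the variance of peak counts in 1 Mb bins was still 2.57 times their mean, against a random median of 1.11. The intervals are therefore too narrow and the p-values too small, to an extent that was not tested. With each block of neighbouring peaks counted once, chromosome 8 had a ratio of 1.17 and was no longer called.

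**Figure D2:**
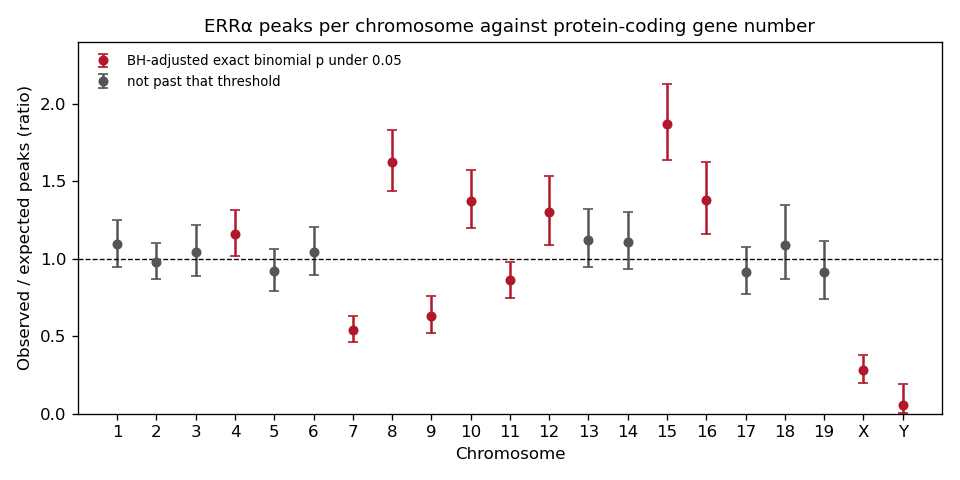
Ratio of observed to expected ERRα peaks (y axis, linear) for each chromosome (x axis), with the expected number taken from the chromosome's share of protein-coding genes; bars are exact (Clopper-Pearson) 95% intervals and the dashed line marks a ratio of 1. Chromosome 15 stands highest at 1.87, and X and Y lie lowest at 0.28 and 0.053; with the span as the expected share X stays low at 0.21, while Y turns to 1.15 and is not called.

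Across the 19 autosomes, chromosomes with more protein-coding genes held more peaks (Pearson r = 0.53, permutation p = 0.018; Spearman rho = 0.61, permutation p = 0.0065). Chromosomes 2 and 7 lay farthest from the median gene number, and without them Pearson r was 0.57 (permutation p = 0.017). The span covered by peaks gave a similar relation, with r = 0.59 and rho = 0.62, and a Benjamini-Hochberg adjusted permutation p of 0.0065 for rho in both relations tested; for Pearson r the adjusted permutation p was 0.018 against genes and 0.015 against span. Chromosomes 1 and 19 lay farthest from the median span, and without them r was 0.54 (permutation p = 0.026). Autosomes are not independent replicates, and these coefficients describe the peak list.

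ERRα peaks were grouped more closely than uniform random placement along each chromosome gives. Such placement takes no account of gene density or of sequence to which reads can be aligned, so the excess cannot be read as particular to ERRα. A neighbouring peak lay within 10 kb of 25.2% of the peaks, against a median of 2.73% and a highest value of 4.65% in 10000 random placements on the same chromosomes (two-sided permutation p = 0.0002, the smallest that the placements can give). Within 1 kb the share was 10.6% against a random median of 0.248%, and within 100 kb it was 50.6% against 24.2%. Joining peaks no more than 10 kb apart gave 2699 separate groups, of which 2413 were single peaks and 286 were runs of 2 peaks or more that held 812 peaks. With a fixed window width and an unknown peak caller, neighbouring binding sites cannot be told from a single broad region listed as several windows.

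Against the same uniform placement, the grouping extended to the scale of megabases. Of the 2558 bins of 1 Mb between the first and last peaks of the chromosomes, 48.1% held no peak, against a median of 29.9% in random placements (two-sided permutation p = 0.0002). Peak-free stretches of more than 10 Mb numbered 11, of which 5 were on X. This number was not compared with random placements. The longest lay on X from 146922626 to 166650075 (19.7 Mb) and on chromosome 16 from 58654251 to 76320100 (17.7 Mb). The longest stretch of all, on X, was not beyond the longest in random placements, whose median was 15.2 Mb (two-sided permutation p = 0.29). That test took the longest stretch over all chromosomes, each keeping its own number of peaks. X was the sparsest, with 0.26 peaks per Mb of span. The test therefore does not judge the stretch on chromosome 16 or on other autosomes, which were not tested by chromosome.

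The densest run of peaks lay on chromosome 8, from 126062651 to 126147675, and held 74 peaks in 85.0 kb, or 29.6% of the peaks of that chromosome. By number of peaks in the surrounding 100 kb, 15 windows tied at 74, and the 10 named by position, from the window at 126098251 to 126098450 to the window at 126106776 to 126106975, all belonged to this run. No random placement gave a run of more than 5 peaks. The peak list held 8 longer runs, with 165 peaks or 5.12% of the list. Besides the run on chromosome 8, 26 peaks lay on chromosome 7 from 66764076 to 66842850, 17 on chromosome 14 from 61552201 to 61581875, 14 on chromosome 3 from 93007826 to 93023475 and 12 on chromosome 4 from 88419676 to 88452075. Shorter runs of 9, 7 and 6 peaks lay on chromosomes 16, 5 and 18, at 3643026 to 3661550, 136099826 to 136104750 and 26162526 to 26165950. These runs, other than the densest, were chosen after their values were seen.

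Peaks recurred at a preferred distance in 3 of the 8 long runs, and only the run on chromosome 4 was evenly spaced. On chromosome 4, all 11 distances between neighbouring window starts were between 2825 and 3000 bp, with a median of 2925 bp. On chromosome 7 distances ran from 1850 to 9375 bp with a median of 1875 bp; 15 of the 25 were within 5% of the median, and all 25 were within 5% of that length from a whole multiple of it. On chromosome 8 distances ran from 350 to 1950 bp with no single step between neighbours, but 63.5% of the 74 peaks had another peak at 1700 bp (within 25 bp), against a median of 27.0% and a highest value of 41.9% in random arrangements of as many windows over the same length. On chromosome 7 the best distance was 3750 bp, at which 92.3% of peaks had another peak, against a highest random value of 46.2%. On chromosome 4 it was 2925 bp, with 75% of peaks against a random median of 33.3% and a highest value of 75%. The share at the best distance exceeded random arrangements for chromosomes 8 and 7 (adjusted one-sided permutation p = 0.0004 each) and for chromosome 4 (adjusted permutation p = 0.00053), with adjustment over the 8 runs. The runs on chromosomes 14, 3, 16, 5 and 18 did not exceed random arrangements, with adjusted permutation p = 0.87 for each.

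**Figure D3:**
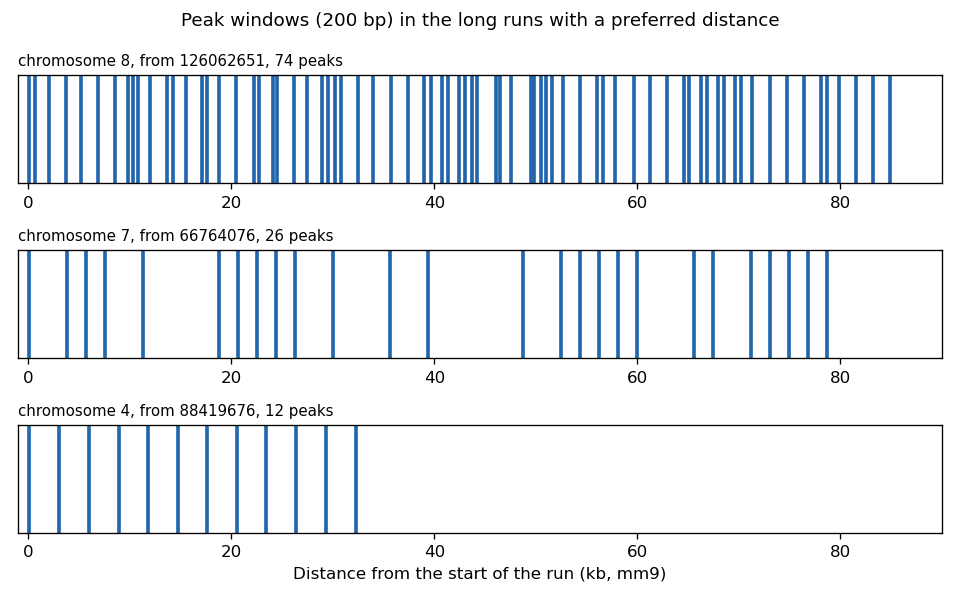
Peak windows (blue bars, 200 bp wide and drawn to scale) in the 3 long runs with a preferred distance, by distance in kb from the first window of the run. The 12 windows on chromosome 4 stand at steps of about 2925 bp, those on chromosome 7 at 1875 bp or its multiples, and many of the 74 on chromosome 8 recur at 1700 bp.

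Leaving out the 8 long runs, 21.1% of the remaining 3060 peaks had a neighbour within 10 kb against a random median of 2.61%, and 48.3% of the 1 Mb bins were empty against 31.7%. The ratio of chromosome 8 to its gene share then was 1.21, and that of chromosome 15, which held no long run, was 1.97. Chromosomes 4 and 11 no longer passed the test without these runs, with ratios of 1.16 and 0.91. Chromosome 11 held no long run: its 204 peaks were unchanged, and its expected number fell from 237 to 225 with the smaller total.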

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

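The number of chromosomes called, 11, ranged from 8 to 12 over the alternatives (8 of 19 with autosomes alone, where 9 of the 11 were autosomes and chromosome 4 lost its call, 12 with the span as the expected share, 9 without receptor genes, 8 with each run counted once and 9 without the long runs). The 12 calls by span shared 6 with the 11 by genes in the same direction: chromosomes 1, 3 and 18 were newly lower, 17 and 19 newly higher, and 11 turned from lower to higher. Chromosomes 10 and 15 were higher in every one of them, and 9 and X were lower in every one that included X. No rows overlapped, so merging changed nothing. The span as the expected share turned the direction of chromosomes 11 (ratio 1.36), 12 (0.89, not called) and Y (1.15, not called). Y turned because 2 peaks define its span, while its share by genes rests on 256 genes of the other build. Whether mm9 holds those genes was not checked. The calls of 7 (0.87) and 16 (1.15) ended. Peak counts were unchanged, so these changes come from the expected shares alone. Chromosomes 11 and 7 held 1609 and 2030 genes over spans of 118 and 146 Mb. Chromosomes 12 and 16 held 679 genes each, over 115 and 94.7 Mb. Chromosome 4 stayed called with the span alone, and its ratio lay between 1.11 and 1.19. Chromosome 11 lost its call without the long runs, of which it held none, and with runs counted once. Chromosome 12 lost its call without receptor genes, and chromosome 8 with runs counted once. Clustering within 10 kb kept its direction and its call in every alternative run, with shares between 10.6% (1 kb window) and 50.6% (100 kb window); placing peaks only within 1 Mb of a peak raised the random median from 2.73% to 3.66%. Empty bins did so too, at 7.49% with 5 Mb bins against a random median of 1.71%. Without the long runs, Spearman's rho between peaks and genes was 0.57, and between peaks and span 0.54; with chromosomes 1 and 19 also left out, the latter was 0.46 and did not pass the test (permutation p = 0.068). The stricter threshold by score was not run, because the list has neither scores nor unequal widths, nor were the alternatives for transcription start sites, gene lists, motifs and scores, or an expected share by chromosome length. No paired analysis was possible because each group has 1 library, which also leaves no replicate to omit. Depth is unknown, so scarcity of peaks on a chromosome is not absence of binding.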

Other observations

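All tests in this part were chosen after the results they bear on had been seen. Peaks were uneven along several chromosomes when each was split at the midpoint between its first and last peak. The distal part of chromosome 15 held 148 peaks and the proximal part 66, or 2.99 and 1.33 peaks per Mb, where the span of all chromosomes averaged 1.27 per Mb. Between 70 and 90 Mb that chromosome had 41 peaks in each 10 Mb. On chromosome 4 the distal part held 163 peaks and the proximal part 64. On chromosome 8 the numbers were 198 and 52, with the run of 74 in the distal part. Chromosomes 17, 14 and 16 leaned the other way, with 102, 98 and 90 peaks in the proximal part and 41, 41 and 48 in the distal part. On X both parts were sparse, with 22 and 18 peaks. Over the 19 autosomes, the distal part held more peaks in 11.

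The runs with a preferred distance were set against 2 explanations. A preferred distance beyond random arrangements was found in 3 of the 8 long runs, which together hold 112 peaks or 3.47% of the list. Reads shared between tandem copies of a repeated unit are a candidate explanation for these runs. A locally higher DNA copy number with no repeat unit does not predict the fixed distance at which 63.5% of the chromosome 8 peaks recur. Binding of ERRα to a site in each copy of such a unit would give the same positions and was not tested, since neither reads nor sequence were used.

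For the other 5 long runs, with 53 peaks, the test decided nothing about a repeat unit of fixed length: all 5 lay at the median of random arrangements, with 0 below it and 0 above it.

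The excess on chromosome 8 was set against the long runs, and that on chromosome 15 against the choice of the expected share. Without the long runs the ratio of chromosome 8 fell from 1.63 to 1.21 (95% interval 1.04 to 1.39), and with each run counted once it was 1.17 (1.00 to 1.37). The run of 74 peaks therefore accounts for much of the excess. Whether any excess remains was not decided, because these intervals treat peaks as independent and are too narrow. Chromosome 15 held no long run. Its ratio was 1.70 (1.49 to 1.93) with the span as the expected share, which argues against the use of gene number as the whole cause. Extra copies of chromosome 15 in this cell line may contribute and cannot be told apart from uneven gene density: its sparser part had a ratio of 1.05 (0.81 to 1.33) by span, and no gene density on mm9 or input signal was used. A concentration of ERRα target genes on the distal part of chromosome 15 stays open and was not tested.

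The scarcity of peaks on X held with both expected shares tried, with a ratio by span of 0.21 (0.15 to 0.28). Other expected shares, such as chromosome length, were not tested. If X were present at 0.5 of the autosomal copy number and peaks followed copies in proportion, a ratio near 0.5 would be expected, and the upper bound by genes was 0.38. That expectation takes X to hold as many sites per gene as the average. Ratios of autosomes ran from 0.54 on chromosome 7 to 1.87 on chromosome 15, so the bound does not decide about the copy number of X. A peak threshold that removes more than a proportional share of sites on a chromosome with fewer copies, and fewer ERRα sites on X, both stay open and were not tested.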
